A study of Saccharomyces cerevisiae with 22 samples.

How the data were processed

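Genomic DNA of 22 libraries from 6 strains of budding yeast (Saccharomyces cerevisiae) was analysed. Per the labels, cells in log phase were flow-sorted, and single-end Illumina reads were made from 4 stages of the cycle: G1, S, and an early and a late fraction of G2. Strains were named by their labels: 2 wild-type strains (replicates 1 and 2, the second with G1 and S libraries only), a sir2 strain, a weakrARS strain, a strain with both labels (weakrARSsir2, called the double mutant) and a strain labelled YAC. The labels do not say whether the stages of a strain came from separate cultures, so the spread between the wild-type strains was the only replicate error. These strains differ at marker genes and mating-type loci, so their SD mixes genotype with replicate spread.

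The deposited values are signal, the coverage per base as whole numbers, made with bedtools on the sacCer3 build, per the submitters' processing notes; the version, the aligner and the handling of duplicate reads are not given in the sources used here. Positions without a read are not listed in the deposited files and were set to 0. Isolated stretches of depth 1 were most often 50 bases long, which was taken as the read length. TEF1 and TEF2, a gene pair of near-identical coding sequence looked at after the data were seen, each had a relative depth of 1.72 to 2.10, so reads with several placements appear to be counted at each of them. For that reason the rDNA depth was not multiplied by the number of reference copies, which departs from the plan.

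Depth was averaged in 5 kb bins. Each library was divided by its median over unique bins, those whose median relative depth over all libraries lay between 0.5 and 1.5 (2188 of 2423 bins, 90.5% of the nuclear genome). The replication profile was log2 of a stage over the same strain's G1 library, centred on its median. The early and late deciles (219 bins each) were taken from the S profile of wild-type replicate 2, and for that strain itself from replicate 1. Intervals of the late-minus-early difference came from 2000 bootstrap draws of the 16 chromosomes for levels (500 for differences), cover spread within a library pair and not between cultures, and were added to the plan after the data were seen. The segments of chromosome XII and the parts of the artificial chromosome were also chosen then. In G2 fractions the replicated share of a region was computed on the assumption that the early decile was fully replicated. Shares above 100 show the error of that estimate, which is not only noise. In late G2 of the YAC strain, XII 720001 to 740000 was at 134.4%. The arm beyond the rDNA was raised there over 104 bins (median log2 ratio 0.196), so the share does not measure replication in it. The replicated share was also added to the plan afterwards.

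Median depth over unique bins ranged from 23.8 to 102.7 per library, or 2380 to 10268 read equivalents per bin; counting error of a log2 ratio was 0.021 to 0.038. Bins were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, an additive model of the sir2 and weakrARS labels, Benjamini-Hochberg threshold 0.05), with the YAC strain as neither label. On simulated data with 200 changed bins among 2188, this test recovered 61 of 100 bins changed by 0.3 at S, 66 of 100 at early G2 and 96 of 100 at late G2, and 100, 96 and 100 of 100 bins changed by 1. It also called 13, 8 and 2 of the 1988 unchanged bins. The simulated noise was independent between strains and bins, with each bin's residual SD. Neighbouring bins of the data are not independent, so these recoveries need not hold for the data. Late-minus-early differences of strains with and without the sir2 label were compared with an exact two-sided permutation test over strains. The same test on the rDNA was added after the data were seen. Sets of bins were placed among 10000 random sets of equal size. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

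Gene names and positions came from the RefSeq table of assembly R64. Centromeres were placed midway between the innermost genes of the left and right arms. All listed genes were found in that table, which names no replication origins. Named regions followed a rule set before the data were examined: all genes of fixed lists, the 5 earliest and 5 latest 20 kb windows of the S profile of wild-type replicate 1, the 5 lowest and 5 highest windows of each strain's difference from wild-type replicate 1 beyond 2 SD, each named by up to 3 genes nearest its midpoint, and up to 10 bins with the smallest adjusted p from limma. The last bin of a chromosome can be short, which is stated where it matters. Bin size, bin value, filter, chromosome ends, chromosome XII, timing classes, left-out strains and rDNA denominators were varied.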

Results

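The series followed DNA replication in yeast strains with and without SIR2, the histone deacetylase that silences the ribosomal DNA repeats, the mating-type cassettes and telomeres. It asked how replication is shared between the rDNA and the rest of the genome. Read depth was measured in cells sorted by DNA content in 22 libraries: G1, S, early G2 and late G2 of 5 strains, and G1 and S of a further wild-type strain. Each strain had 1 library per stage, and the wild-type group had 2 strains at G1 and S. There were no replicates of the other genotypes. The median depth of unique bins ranged from 23.8 to 102.7 per library, or 2380 to 10268 read equivalents per 5 kb bin; the sir2 libraries were the deepest, from 84.2 upward.

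The SIR2 gene was covered at 0.00 to 0.01 of the typical bin in the 8 libraries labelled sir2 or weakrARSsir2, and at 0.75 to 1.06 in the other 14. SIR3, SIR4, FOB1 and RAD52, genes of silencing, rDNA fork arrest and recombination, were present in all libraries. The wild-type strains differed at marker genes: LYS2 was at 0.00 in G1 of replicate 1 and at 0.96 in G1 of replicate 2, while LEU2, MET17 (listed as MET15) and URA3 were at 0.00 to 0.01 in replicate 2. MATALPHA1 had a relative depth of 2.15 in replicate 1 and 0.31 in replicate 2 in G1. The weakrARS strain and the double mutant were at 0.00 over ASP3-1 to ASP3-4, the asparaginase genes within the rDNA region of chromosome XII, whose relative depth was 4.90 in G1 of wild-type replicate 1.

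In wild-type S cells the depth ran from regions around VII 480001 to 500000 (COG7, RPN14, PMC1; 0.58 above the median on the log2 scale), XIII 260001 to 280000 (CDC5, MIX17, YPT7; 0.57) and II 240001 to 260000 (DSF2, UGA2, FLR1; 0.57) down to X 480001 to 500000 (GEA1, CPR7, RAV1; -0.35) and XV 940001 to 960000 (KRE5, ALA1, MRS2; -0.35) in replicate 1. Bins within 10 kb of a centromere had a median of 0.52 in this strain, above all 10000 random sets, as had bins with tRNA genes, with 0.26. Bins within 20 kb of a chromosome end had a median of -0.24 in replicate 1, below all random sets, and of -0.11 in replicate 2. Bins with histone genes had a median of 0.36 in wild-type replicate 1 (percentile 96.9 of random sets) and 0.37 in weakrARS (percentile 98.4). Bins with replication initiation genes had a median of 0.012 in replicate 1 (percentile 53.5), and of 0.10 with 10 kb bins. The late-minus-early difference was -0.75 ± 0.003 (SD, n = 2 wild-type strains), and the strains' profiles correlated across bins with r = 0.93; bins are not independent replicates.

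The timing contrast between late and early regions in S cells was -0.79 in sir2, -0.73 in weakrARS, -0.73 in the double mutant and -0.67 in the YAC strain. All 4 lay outside the SD of the wild-type strains. That SD rests on 2 values, each scored on timing classes from the other strain, so it compares different bins. The bootstrap intervals of the wild-type values, -0.76 to -0.74 and -0.78 to -0.73, are wider than that SD. Lying outside it therefore does not set a strain apart. With timing classes from wild-type replicate 1, weakrARS minus wild type (0.021) was 0.0017, within that SD. In that setting replicate 1 was itself scored on classes from its own S profile, which the main setting avoids. The strains without SIR2 averaged -0.76 and those with it -0.73, a difference that an exact two-sided permutation test over the 6 strains did not separate (p = 0.533; the smallest p its 15 splits allow is 0.067). Some windows differed from wild-type replicate 1 in both strains without SIR2: IV 40001 to 60000, with GCS1, HO and SHS1, had a log2 difference of -0.22 in sir2 and -0.32 in the double mutant, while XII 200001 to 220000 (RSC58, SMF3, RAD5) differed by 0.19 in both. X 700001 to 720000, with the cell wall genes DAN1 and DAN4, differed by 0.18 and 0.20. The YAC strain, with SIR2, had S profile values of 0.51 and 0.33 in the last pair, against 0.064 and -0.023 in wild-type replicate 1. The weakrARS strain, also with SIR2, had 0.075 and -0.058. The S profile of the YAC strain was unlike the others, so these values do not decide whether the rises depend on the loss of SIR2. In the window with HO the YAC value was -0.034, against 0.084 in wild-type replicate 1, -0.14 in sir2 and -0.24 in the double mutant. IX 360001 to 380000 (EGH1, PAN1, PRI1) was the highest in sir2, with 0.20, and VIII 1 to 20000 (ARN2, PAU13, PXP3) had 0.18. XII 560001 to 580000 (FRE1, CDC123, CPR6) differed by 0.17 in the double mutant and IX 380001 to 400000, with the flocculin gene FLO11, by 0.16. In weakrARS the lowest difference was -0.21 at XV 840001 to 860000 (RDL1, RDL2, HUA2), a window with -0.20 in the double mutant; the YAC strain, without that label, had an S profile value of -0.025 there, against 0.21 in wild-type replicate 1. XIV 20001 to 40000 (FIG4, PFA3, LEM3) followed with -0.14. The YAC strain differed most, by 0.62 at III 1 to 20000, which holds the silent mating-type gene HMLALPHA2, by 0.62 at X 480001 to 500000 (GEA1, CPR7, RAV1) and by -0.39 at X 80001 to 100000 (ATG27, PFD1, RPL17B). Between the wild-type strains such differences ran from -0.23 to 0.19, and none of the differences named here has a replicate. With limma no bin passed for the sir2 or the weakrARS label at S (13 and 46 of 2188 bins at an unadjusted p under 0.05). These counts rest on single strains: without the YAC strain 5 bins passed for sir2, with 274 and 224 at an unadjusted p under 0.05, and without weakrARS the latter were 3 and 0.

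To ask whether replication was complete when cells reached a G2 content of DNA, late regions were compared with early ones. In early G2 cells they were less complete in sir2 than in wild type, weakrARS and the double mutant. The late-minus-early difference was -0.20 (95% chromosome bootstrap interval -0.22 to -0.18) in sir2, against -0.059 (-0.070 to -0.045) in wild-type replicate 1, -0.042 in weakrARS and -0.072 in the double mutant. If the early decile is taken as fully replicated, the late decile was 74.4% replicated in sir2, 92.0% in wild type, 94.3% in weakrARS and 90.2% in the double mutant. Of 545 windows, 135 were under 80% replicated in sir2, 10 in wild type, 7 in weakrARS and 20 in the double mutant. The YAC strain, which has SIR2, had a difference of -0.20 and 195 such windows, the lowest against wild type being IV 760001 to 780000 (RPA14, HOM2, CPR1; 32.9% against 92.4%).

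**Figure D1:**
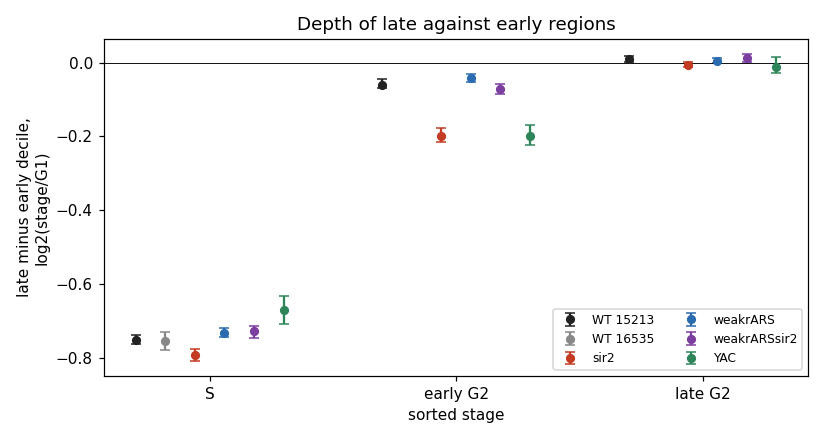
Points give the mean log2(stage/G1) of late-decile bins minus that of early-decile bins for each strain and sorted stage, and bars are 95% bootstrap intervals over chromosomes within 1 library pair. At early G2 the sir2 and YAC strains sit at -0.20, below wild type at -0.059.

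Several of the windows with the lowest difference of sir2 from wild type at early G2 are given here. At IV 20001 to 40000 (GUD1, AIM6, ADY3) 54.7% was replicated in sir2, 90.3% in wild type, 72.9% in the double mutant and 45.3% in the YAC strain. II 560001 to 580000 (TYR1, UBS1, POP7) was at 55.9%, 89.4%, 80.9% and 64.5%, and IV 1080001 to 1100000 (PIB1, RAD34, SSF2) at 57.6%, 90.4%, 82.9% and 73.6%, so the YAC strain, with SIR2, was also low in them. The lowest window, VI 260001 to 270161 with IRC7 near its middle, was at 40.1% in sir2, 84.1% in wild type, 62.6% in the double mutant and 89.9% in the YAC strain, but its mean gives equal weight to a last bin of 161 bases. No window exceeded 2 SD upward in sir2, while 48 did so downward. The counts were 0 and 51 in the YAC strain, and in sir2 at S 51 upward and 1 downward. All are relative to each profile's median, and at S the direction of limma's bins changed with the centring, as given below. The window most above wild type in weakrARS at early G2, XIV 760001 to 780000 (PDR18, HXT17, MAN2), was 90.2% replicated there. It was 76.8% replicated in wild type, 60.4% in sir2 and 35.7% in the YAC strain. The double mutant lay above sir2 by 0.13 in the late-minus-early difference (0.12 to 0.14), and the effect of losing SIR2 was 0.11 smaller on the weakrARS background (0.095 to 0.12); there is 1 library per genotype, so this was not tested between cultures. Over strains the sir2 label gave a mean of -0.13 against -0.10 (exact two-sided permutation p = 0.5, the smallest of 10 splits being 0.1). The YAC strain, at -0.20, was the only strain with SIR2 that lay below the double mutant, at -0.072. With limma no bin passed for sir2 (27 at an unadjusted p under 0.05, all 27 lower) or weakrARS (12). Both counts are below a share of 0.05 of the 2188 bins, and neighbouring bins are not independent. The common direction of the 27 was therefore not tested. The first-ranked bin for sir2 was the last 161 bases of chromosome VI (log2 difference -0.67, adjusted p = 0.13). Without the YAC strain 3 passed for sir2, with 288 at an unadjusted p under 0.05 (268 lower) and 107 for weakrARS. Without wild-type replicate 1 limma called 1 bin for sir2, with 51 at an unadjusted p under 0.05 (24 lower) and 425 for weakrARS. The counts thus changed without single strains. The lower direction for sir2 was lost in the fit without wild-type replicate 1, where the YAC strain alone carries neither label. It was weaker in the trended robust fit of all strains, with 10 of 17 bins lower at an unadjusted p under 0.05.

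**Figure D2:**
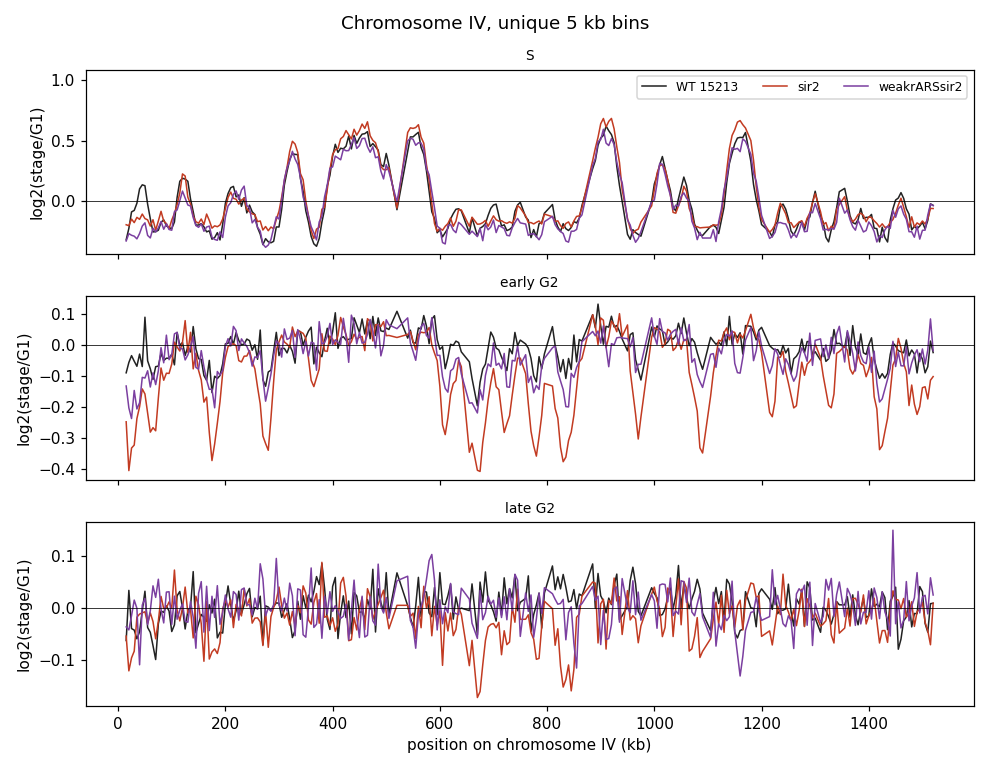
Lines give log2(stage/G1) along chromosome IV in unique 5 kb bins, by position in kb, for wild-type replicate 1, sir2 and the double mutant at S, early G2 and late G2 (vertical scales differ). At early G2 the sir2 line falls furthest in the late regions, including 1080001 to 1100000 at a log2 ratio of -0.30.

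By late G2 the late decile was near completion in all 5 strains, from 98.6% in the YAC strain to 101.9% in the double mutant, and no window was under 80%. Each strain's own lowest window was at 80.5% in sir2, 84.9% in the YAC strain, 89.2% in weakrARS, 90.3% in the double mutant and 92.7% in wild type. The sir2 strain differed from wild type by -0.016 in the late-minus-early difference (-0.027 to -0.0079). Among its lowest windows relative to wild type were IV 660001 to 680000 (TMN2, TRS85, ARP10; -0.15) and II 560001 to 580000 (TYR1, UBS1, POP7; -0.12). Their log2 ratios to G1 were -0.13 and -0.098 in sir2, 0.016 and 0.018 in wild type, -0.017 and -0.005 in the double mutant, and -0.10 and -0.017 in the YAC strain, whose own lowest window against wild type was the first of them. IV 840001 to 860000 (REF2, CAB5, CBS2; -0.12) and XIV 380001 to 400000 (ESBP6, SPC98, NAF1; -0.11) followed. The highest window was XIV 60001 to 80000 (CLA4, TRF5, TOS6; 0.09). The 1 bin that limma called for sir2 was the last 218 bases of chromosome I (230001 to 230218, log2 difference -0.39 ± 0.067 SE, adjusted p = 0.015). It was not called without wild-type replicate 1. Leaving out chromosome ends removes this bin, so that setting does not test it. Without sir2, weakrARS or the double mutant, the error rests on wild-type replicate 1 against the YAC strain alone. Those fits do not show whether the call depends on the strain left out. VII 1040001 to 1045000, with TAF1, RTT102 and RNH70, followed at -0.16 and did not pass (adjusted p = 0.31). No bin was called for weakrARS (115 at an unadjusted p under 0.05, close to the share of 0.05 of 2188 bins that no effect would give). The permutation contrast was 0.002 (exact two-sided p = 0.9).

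The rDNA, which encodes ribosomal RNA, was compared with unique DNA to ask how replication is shared between them. In S cells it lay above its G1 level in both strains without SIR2 and below it in the 4 strains with SIR2. Its depth over the median bin went from 87.4 in G1 to 119.1 in S in sir2, a ratio of 1.36, and from 69.5 to 75.2 in the double mutant, a ratio of 1.08. In wild type the ratio was 0.873 ± 0.075 (SD, n = 2), in weakrARS 0.836 and in YAC 0.893. On the log2 scale sir2 was 0.65 above the wild-type mean and the double mutant 0.31, against a wild-type SD of 0.12, and the double mutant minus sir2 was -0.33. With late G2 in place of G1 the sir2 value was 0.40, against wild-type replicate 1 alone, since replicate 2 has no late G2 library; over G1 the log2 ratios were 0.45 in sir2 and -0.11 in replicate 1. The double mutant minus sir2 was -0.17 over late G2, and with the early decile as denominator the latter was -0.21. Both strains without SIR2 lay above all 4 with it (exact two-sided permutation p = 0.067, the smallest the 15 splits can give). In G1 the rDNA depth was 102.9 and 163.7 in the wild-type strains, 104.3 in weakrARS and 195.8 in YAC. At late G2 the ratio was 1.16 in sir2, 1.03 in wild type, 0.944 in weakrARS and 1.03 in the double mutant. In the YAC strain the ratio was 0.68 at early G2 (percentile 0.14 of unique bins).

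**Figure D3:**
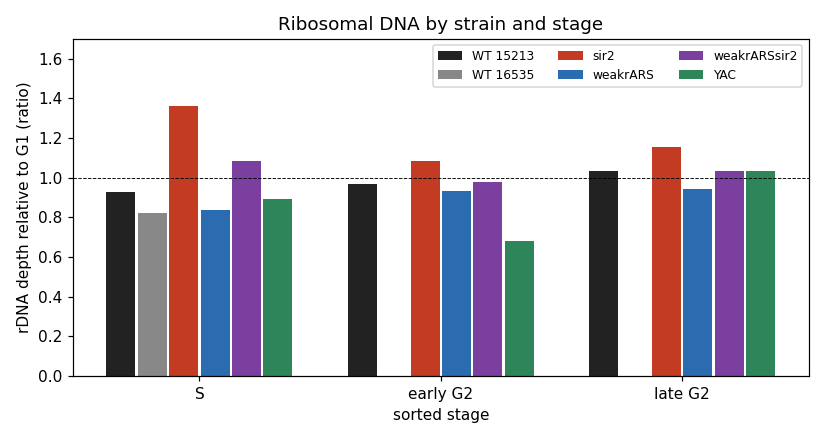
Bars give the depth over the 35S rDNA units relative to the same strain's G1 library, by strain and sorted stage, 1 library pair per bar; the dashed line is a ratio of 1. In S the sir2 bar is at 1.36 and the double mutant at 1.08, and the 4 strains with SIR2 are below 1.

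The other repeats were listed to see whether they moved with the rDNA. CUP1, the copper metallothionein array, had a relative depth of 12.9 and 13.0 in G1 of wild-type replicate 1 and sir2, and 10.2 and 10.9 in S. ENA1, a sodium pump gene of a tandem array, was at 4.26 to 5.24 over all libraries. From G1 to S it went from 4.48 to 4.94 in sir2 and from 4.49 to 4.91 in the double mutant. In the YAC strain, with SIR2, it rose most, from 4.32 to 5.24. It went from 4.36 to 4.40 and from 4.47 to 4.69 in wild-type replicates 1 and 2, and from 4.45 to 4.44 in weakrARS. The subtelomeric helicase gene YRF1-1 was at 17.7 in wild-type replicate 1 and 17.3 in sir2 in G1, and at 16.5 and 17.2 in S. The slope of a strain's profile on that of wild-type replicate 1 at early G2 was 1.39 in sir2, 0.54 in weakrARS, 0.75 in the double mutant and 1.53 in YAC, with correlations across bins of 0.52 to 0.68. The ratio of the profiles' SDs, from which counting noise was not removed, was 2.04, 0.903, 1.199 and 2.93. At S the slopes were 1.01, 0.975, 0.955 and 0.788.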

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

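All tests of explanations in this part were chosen after the results were seen. The effect of losing SIR2 on the late-minus-early difference had opposite signs with and without the weakrARS label at S and at late G2: the effect with the label minus that without was 0.043 at S and 0.023 at late G2. The effect with the label was close to 0, at 0.0046 at S and 0.0075 at late G2. With 1 kb bins at S the effect without the label was -0.048 and the effect difference 0.047, so the signs were no longer opposite. Each rests on single libraries, and the difference was not tested between cultures. Reads on the contig of the artificial chromosome, which the comparisons do not use, had a mean depth of 0.27 of the median bin in G1, 0.31 in S, 0.24 in early G2 and 0.29 in late G2 of the YAC strain.

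The low late regions of sir2 at early G2 were set against the sorting gate and against the loss of SIR2. S cells of average composition in the gate would make the early G2 profile a straight line on the strain's S profile, but its r squared, 0.466, was 0.482 of what counting noise allows, which argues against this as the whole cause. A gate set too early, with replication complete by late G2, would leave nothing at late G2; over the 54 windows least replicated in the double mutant at early G2, the late G2 mean of sir2 was lower than in wild type and weakrARS (by -0.053 against the lower of them), with 50 of the 54 windows below wild type. A gate that took the last S cells at both G2 stages stays open. Loss of SIR2 by itself could not be decided, since the double mutant had -0.072 and the YAC strain, with SIR2, -0.20.

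The raised rDNA in S of the strains without SIR2 was set against a low G1 library, the S gate and chance. Against late G2 in place of G1 the lowest strain without SIR2 had a log2 ratio of 0.067 and the highest with SIR2 -0.16. The gap is larger than the 0.12 SD of the wild-type ratios to G1, which argues against a low G1 library as the whole cause. In sir2 the ratio to G1 was also above 1 at early G2 (1.09) and late G2 (1.16), so a low G1 value as a part of its rise stays open. The rDNA lay at percentile 61.7 or more of its own library's unique bins without SIR2 and at 40.9 or less with it; the gap is smaller than the wild-type SD of 23.5, so a different S gate stays open. Of the 15 splits of the strains, 1, the real one, gave a difference as large (0.49), and 15 splits are too few for a share under 0.05. No biological explanation of the rDNA values was tested.

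The YAC strain's S profile was unlike the others. A gate that only rescaled the profile would keep its correlation across bins with wild-type replicate 1. That correlation was 0.766, against 0.932 for the lowest of the other strains. A gate at another part of S phase could change the shape of the profile as well, so a different gate stays open. CUP1 was at 0.89 or less in this strain and at 10.1 or more in the others, consistent with another strain background as the source. The background and the artificial chromosome come together in this strain, and their effects were not separated.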

How the results depend on the processing

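Leaving the YAC strain out of the permutation and taking late G2 as the rDNA denominator were chosen after seeing the data. Changes were judged against the SD of the wild-type strains at S, which is 0.0032 for the timing contrast, and against bootstrap intervals at G2. For the timing contrast that SD compares different bins and is narrower than the wild-type bootstrap intervals, so small changes at S count as moved. Of the late-minus-early values 131 stayed within these limits, 40 moved and 1 reversed; of the rDNA values 62 stayed and 3 moved; of the class medians 325 stayed and 107 moved, and none reversed. The sir2 minus wild type value at early G2 lay between -0.13 and -0.15 under every setting run. The causes of the changes below were not tested. With 1 kb bins sir2 minus wild type at S was -0.048, the double mutant minus wild type 0.018, YAC minus wild type 0.071 and the difference between the SIR2 effects 0.047 (0.093 at early G2), and the double mutant minus sir2 was 0.11 at early G2. The Late-minus-early difference, weakrARSsir2 minus sir2, lateG2, was then 0.0058. With 10 kb bins weakrARS minus wild type at S was 0.014, YAC 0.097 and the effect difference 0.052. With the median depth of each bin weakrARS at S was 0.015, YAC 0.075 and the double mutant minus sir2 0.061. Without the depth filter, S values were -0.021 for sir2, 0.035 for the double mutant, 0.087 for YAC, 0.035 for the effect difference and 0.056 for the double mutant minus sir2, the last being 0.11 at early G2. The stricter filter gave 0.039 for the effect difference and 0.077 for YAC at S, and leaving out chromosome XII 0.076 for YAC. Without chromosome ends the double mutant differed at S by 0.037 from wild type and 0.072 from sir2, YAC by 0.077, and the effect difference was 0.048. With quintiles the Late-minus-early difference, weakrARS_15985 minus WT, S, was 0.0071, and S values were 0.014 for the double mutant and 0.050 for the double mutant minus sir2. Timing classes from wild-type replicate 1 gave -0.031 for sir2, 0.0017 for weakrARS, 0.032 for the double mutant, 0.11 for YAC and 0.062 for the effect difference at S. At early G2 they gave 0.032 for weakrARS, 0.0087 for the double mutant (reversed from -0.013), 0.12 for the effect difference and 0.16 for the double mutant minus sir2, and at late G2 0.024, 0.031 and, for the double mutant minus sir2, 0.052. In this setting replicate 1 was scored on classes from its own S and G1 libraries, which the main setting avoids. It is the only wild type at G2 and shares that G1 library, so the values against wild type, the reversal included, are not an independent check.

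The SIR2 contrast of the late-minus-early difference, lateG2, turned from 0.0019 to -0.0021 with 10 kb bins, -0.0034 with quintiles and -0.0042 without the YAC strain. At S and early G2 it kept its sign. With the YAC strain (-0.20) set aside, sir2 (-0.20) and the double mutant (-0.072) both lay below wild type (-0.059) and weakrARS (-0.042) at early G2. With profiles centred on the early decile, limma at S gave 36 bins for sir2 (34 lower) and 15 for weakrARS (0 lower) at an unadjusted p under 0.05. Centred on the median they were 13 (6 lower) and 46 (46 lower), so these directions rest on the centring. Without the YAC strain limma called 5 bins for sir2 at S, 3 at early G2 and 3 at late G2, and 1 for weakrARS at late G2. At early G2 the trended robust fit called 1 bin for sir2, as did the fit without wild-type replicate 1. At late G2 the sir2 count was 3 without chromosome XII and 3 with the trended robust fit, and 0 with 1 kb bins, 10 kb bins, median depth, no filter, no chromosome ends, early-decile centring, each factor alone, without wild-type replicate 1 and without each of sir2, weakrARS and the double mutant, with 29 to 353 bins at an unadjusted p under 0.05; for weakrARS 1 bin passed without the filter. A group left with 1 strain was assumed to vary like the others. At G2 the error of fits without sir2, weakrARS or the double mutant rests on wild-type replicate 1 against the YAC strain alone. Leaving out chromosome ends removes the bin that the main fit called for sir2 at late G2. The rDNA contrast of sir2 at S was 0.40 over late G2, where the wild-type group is also reduced to replicate 1, and the double mutant minus sir2 was -0.21 with the early decile as denominator and -0.17 over late G2. With 20 kb bins the slopes at early G2 were 1.86 in sir2, 0.72 in weakrARS, 0.976 in the double mutant and 2.09 in YAC, and at late G2 0.203 in weakrARS, 0.145 in the double mutant and 0.199 in YAC. As ratios of SDs they were 1.03 in YAC at S, 2.04, 0.903, 1.199 and 2.93 in the same order at early G2, and 1.11, 1.08, 1.04 and 1.67 at late G2. With 10 kb bins the S medians of wild-type replicate 1 were 0.40 for histone genes and 0.10 for replication initiation genes, and the late G2 median of chromosome XII before the rDNA in YAC was 0.014. GC correction and classes by distance to replication origins were not run, since neither a genome sequence nor origin positions were at hand. Depth limits single bins at late G2, where the counting error of 0.031 is close to the wild-type profile SD of 0.036.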

Other observations

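The artificial chromosome of the YAC strain was unevenly present and unevenly replicated; its parts were chosen after the data were seen. Relative depth in G1 was 0.72 in the first 5 kb, 0.38 from 5 to 75 kb, 0.33 from 75 to 165 kb and 0.030 from 185 to 245 kb. At early G2 the part from 5 to 75 kb was 92.2% replicated and that from 75 to 165 kb 42.4%, at percentile 3.98 of unique yeast bins; at late G2 they were at 129.2% and 107.6%, and the first 5 kb at 124.9%, so the measure runs well past 100 on this contig.

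In late G2 the arm of chromosome XII beyond the rDNA had more depth than in G1 in the YAC strain, with a median of 0.20 over 104 bins, against 0.020 before the rDNA (0.014 with 10 kb bins). In the other 4 strains the same arm lay between -0.003 and 0.006. The highest windows there were 720001 to 740000 (EXG1, HRI1, ECM38) and 780001 to 800000 (JIP3, MID2, CHS5), both 0.23 above wild type. The step, in 100 kb segments chosen after the data were seen, lay between the segments from 400001 to 500000 (0.023) and 500001 to 600000 (0.20). At early G2 the arm was split: segment medians were 0.090, 0.044 and 0.059 from 500001 to 800000, and -0.38, -0.33 and -0.24 from 800001 to 1100000.

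The weakrARS strain and the double mutant shared a stretch without reads at II 556550 to 558196 (AMN1). LYS2 was at 0.00 or 0.01 in these strains and also in wild-type replicate 1 and sir2. The 2-micron plasmid had a relative depth of 18.3 in G1, 40.7 in S, 21.4 in early G2 and 39.0 in late G2 of sir2, and of 6.68, 10.6, 5.98 and 11.0 in wild-type replicate 1. The mitochondrial genome was at 20.5 in G1 of the YAC strain and at 0.68 in G1 of sir2.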
